A study of Mus musculus with 19 samples.

How the data were processed

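The series holds 16 libraries of ribosome-bound mRNA from mouse striatum, 4 in each of 4 groups: D1 and D2 spiny projection neurons, each at 42 days and at 2 years of age. All mice were female, per the labels. The design text calls the 4 libraries of a group biological replicates, so the spread between them was taken as biological and technical together. The labels give no batch, litter or pairing, and the replicate numbers used here follow the order of the records and only name a library, so nothing was paired. The labels do give an index sequence per library, and the second part of the index of the old D1 libraries is shared with no other group, as is true of young D2. Old D2 shares its second part with young D1, and first parts are shared between groups only within an age. Index and age therefore cannot be told apart in either kind. A further 3 samples are ribosome profiling of NIH-3T3 cells, a mouse fibroblast line, with 100 uM paraquat, a small interfering RNA against Abce1 or a control one; they are not analysed here.

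Ribosomes tagged with a green fluorescent L10a protein were pulled down with their mRNA, and libraries were made from amplified cDNA with the NuGEN Ovation V2 kit, per the labels' protocols. The authors used STAR 2.5.1b and RSEM 1.2.20 with genome build mm10, per the submitters' processing notes. The deposited tables hold, for each library, RSEM expected counts per gene and per isoform, which are estimated counts of fragments and need not be whole. They also hold TPM as the authors' RSEM run gave it, and an abundance-weighted length of each gene in bases, per the file headers. The annotation release, read length, trimming and strand setting are not given in the sources used here. There are 39017 genes and 94647 isoforms in each library's tables.

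RSEM shares a fragment that matches several genes or isoforms among them by a model. Values of genes with near-identical copies or many processed pseudogenes, such as ribosomal protein and respiratory chain genes, are therefore uncertain, as are isoform values. Genes that overlap on opposite strands could share fragments, because strand use is not known. The kit amplifies cDNA without molecular identifiers, so copies of a molecule are counted repeatedly, and bounds from a floor of 3 counts cover counting error only.

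Names, positions and transcript types came from GENCODE M21, an annotation of GRCm38 (the assembly behind mm10), matched by gene and transcript ID without version. Of the 39017 genes, 37607 matched, and of the 94647 isoforms, 91225 matched and held at least 98.8% of the counts in every library. The file's isoform length equalled that in GENCODE M21 for 86.6% of matched isoforms. Start and end positions are 1-based.

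Expected counts were rounded to whole numbers, since 20.0% of the nonzero gene values were not whole. Genes were kept with edgeR's filterByExpr (edgeR 4.0.16, limma 3.58.1, R 4.3.3), library sizes were scaled by TMM, and edgeR's robust quasi-likelihood test was fitted to all 16 libraries with 1 mean per group. The contrasts were old against young within each neuron type, the difference between those age changes, and D1 against D2 at each age. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The adjusted p-values of genes below are from this test, and a log2 fold change comes with its standard error (SE).

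For every comparison, genes to describe were taken from a rule: among called genes with a regular symbol, a mean TPM of at least 5 in the higher group and no overlap between the 4 values of each group (not asked of the difference of age changes), the 10 with the largest change in each direction. Up to 3 called members per direction of each gene list, by smallest adjusted p, and Drd1, Drd2, Tac1, Penk, Adora2a, Pdyn and Abce1 were added. The text describes a part of these, picked after their values and their results under the alternatives were seen. Tmem254a and Tmem254b, and the histone gene Hist1h4h, met the rule but share sequence with near-identical copies and were left out. Some other genes that met the rule are not reported, and they are not among the gene values tested for outlying samples.

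Gene lists were tested with limma's camera on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The lists covered markers of D1, D2 and all spiny projection neurons (SPN), astrocytes, oligodendrocytes, microglia, ependymal cells, cholinergic, GABAergic and glutamatergic neurons. They also covered immediate early genes, interferon and MHC class I, antioxidant, respiratory chain, mitochondrially encoded, ribosomal protein, ribosome rescue, nonsense-mediated decay, endoplasmic reticulum stress, heat shock, p53 target, lysosome, postsynaptic, immature neuron, collagen and cholesterol synthesis genes. These are 26 lists with at least 3 tested members. Lists for oligodendrocyte precursors and for endothelial and mural cells had 2 tested members each and were not tested.

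For isoforms, 3 summaries per library were compared between ages by exact two-sided permutation tests of 4 against 4, whose smallest p is 0.0286. The first was the median log2 of RSEM's abundance-weighted gene length relative to the mean over libraries. The second was the share of the counts of protein-coding genes that fell on isoforms with no coding sequence. The third was the part of that share on isoforms with at least 80% of their bases inside the 3' UTR (untranslated region) of a coding isoform of the same gene. Genes with an expected count of 0 in a library were left out of that library's median length, a choice the plan had left open. Changed isoform use was tested per gene with edgeR's diffSpliceDGE and Simes p-values on rounded isoform counts.

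The grouping, contrasts, tests, rule for naming, gene lists and most alternative settings were fixed before the data were examined. The alternatives cover scaling, filters, DESeq2 1.42.0, fits on the compared groups alone, TPM in place of counts (pseudocount 1) and each library left out in turn. Chosen after seeing the data were removal of each library's trend over GC content and length, limma-voom with library weights (planned for the difference of age changes alone), leaving out the library with the fewest genes in young D1 and in old D1 together, and keeping genes at 0 in the length summary.

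The steps were tested on simulated negative binomial counts with the library sizes of the real ones. Each gene had 1 mean and 1 spread, taken over all real libraries, and 200 genes were changed in old D1 alone. The simulation held no extra spread and no trend over GC content in old D1. Its false calls therefore need not match those of the real D1 comparison. For age in D1 the gene test recovered 2% of genes changed 2-fold and 41% of genes changed 4-fold, out of 13601 genes run, with 1 false call. For the difference of age changes it recovered 1% and 18%. For D1 against D2 at 2 years it recovered 3% and 45%. The isoform test for age in D1 recovered 13.6% of genes in which isoforms with an abundance ratio of at least 4 were swapped and none with a smaller ratio, in 5962 genes run. A gene below the threshold is therefore not shown to be unchanged.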

Results

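Translating ribosome affinity purification (TRAP) was used to read the ribosome-bound mRNA of the 2 kinds of spiny projection neurons (SPNs) of the mouse striatum. D1 neurons carry the dopamine receptor Drd1 and D2 neurons carry Drd2, and each kind expressed the tagged ribosomal protein L10a under the control of its own receptor gene. There are 4 libraries each of young D1, young D2, old D1 and old D2 neurons, where young is 42 days and old is 2 years. The libraries hold 45875518, 39563383, 56890627 and 44317291 assigned fragments (young D1), 39555507, 55439700, 48154571 and 51091060 (young D2), 34844870, 50379824, 40072192 and 34974227 (old D1) and 42797909, 51464606, 70903004 and 27484038 (old D2). Values are TPM as mean ± SD of 4 libraries, fold changes are log2 with the SE, and an adjusted p is from the two-sided edgeR test over 13926 genes.

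The old D1 libraries stand apart from the other 12. They held a count for 11616, 11875, 13676 and 10356 genes against 12766 to 14974 elsewhere. Their mean fragment length was 150 to 163 bases against 169 to 194. The most abundant gene, the ribosomal RNA-like Gm42418, took 4.45 to 5.41% of their counts against 9.76 to 18.2%. Their mean correlation with libraries of their own group was 0.748 to 0.792 against 0.822 to 0.881. The common dispersion over all libraries was 0.956, a biological coefficient of variation of 97.8%. The genes of the Y chromosome looked at, Ddx3y, Eif2s3y, Kdm5d and Uty, stood at 0 TPM in every library, all of which are labelled female. Xist ran from 0 to 2.82 TPM and gives no positive sign of sex.

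Which genes distinguish D1 from D2 neurons in young mice was asked first. The D1 side held Drd1 (284 ± 36.7 against 8.31 ± 2.54; log2 5.23, SE 0.32, adjusted p = 6.93e-09), the substance P precursor Tac1 (1616 ± 324 against 122 ± 9.97; log2 3.86, SE 0.28, adjusted p = 4.85e-08), the dynorphin precursor Pdyn (82.2 ± 9.87 against 2.52 ± 1.63; log2 5.15, adjusted p = 2.12e-06) and the muscarinic receptor Chrm4 (88.6 ± 15.9 against 1.08 ± 1.13; log2 6.38, adjusted p = 1.34e-05). The largest difference with a small error was Eya1, a transcription coactivator, at 573 ± 130 against 3.43 ± 1.60 (log2 7.56, SE 0.43, adjusted p = 3.64e-09). The D2 side held Drd2 (3116 ± 443 against 19.9 ± 15.2; log2 -7.22, SE 0.87, adjusted p = 1.11e-04) and the enkephalin precursor Penk (4270 ± 377 against 119 ± 35.9; log2 -5.06, SE 0.50, adjusted p = 8.03e-06). For each of these genes all 4 libraries of one kind lay above all 4 of the other. Chance gives this in 2.86% of cases for a gene picked without seeing its values. The genes described here were picked after their values were seen, so the separation adds no further support. The adenosine receptor Adora2a, at 547 ± 122 in D2 and 10.01 ± 5.15 in D1 (log2 -5.63, SE 1.27), missed the threshold with an adjusted p = 0.0614 and passed it with DESeq2 (adjusted p = 0.00186), with a range over the alternatives from 1.57e-06 to 0.441.

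In young mice 57 genes differed between the kinds, 28 higher and 29 lower in D1, with 837 at an unadjusted p under 0.05. Of the 10 D1 markers on the fixed list 9 were higher in D1 (camera adjusted p = 5.23e-51; adjusted p = 4.22e-07 with an estimated correlation). Of the 9 tested D2 markers 7 were lower in D1, and 9 when adjusted over the list alone (adjusted p = 8.98e-27; adjusted p = 1.11e-06 with an estimated correlation). Cholinergic interneuron markers were lower in D1 as a list (adjusted p = 1.01e-07; adjusted p = 0.00241 with an estimated correlation). Lists that passed only with the preset correlation were astrocyte markers, higher in D1 (adjusted p = 0.00201; adjusted p = 0.114 with an estimated correlation), and respiratory chain genes, higher (adjusted p = 1.21e-04; adjusted p = 0.213 with an estimated correlation). So were ribosomal proteins, higher (adjusted p = 2.80e-04; adjusted p = 0.356 with an estimated correlation), cholesterol synthesis, higher (adjusted p = 0.00446; adjusted p = 0.105 with an estimated correlation), pan-SPN markers, lower (adjusted p = 6.38e-04; adjusted p = 0.144 with an estimated correlation), and heat shock genes, lower (adjusted p = 0.0416; adjusted p = 0.213 with an estimated correlation). The other 17 lists did not pass.

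Of the genes tested within 200000 bases of the receptor genes, 3 differed between the kinds in young mice and Hrh2, beside Drd1, was not called (log2 1.43, adjusted p = 0.999). On GRCm38 (GENCODE M21), Drd1 lies at chr13:54051183-54055705 and Sfxn1, a mitochondrial carrier, at chr13:54071869-54108342; Sfxn1 stood at 192 ± 28.4 in young D1 and 12.4 ± 3.59 in young D2 (log2 4.07, adjusted p = 2.9e-08). Drd2 lies at chr9:49340627-49408177, with Ankk1 at chr9:49415194-49427021 and Ttc12 at chr9:49436963-49486225. Ttc12 stood at 0.85 ± 1.27 in young D1 and 218 ± 49.1 in young D2 (log2 -8.02, adjusted p = 0.00207), a call that ends when no count filter is applied (adjusted p = 0.0803). Ankk1 had no count in young D1 and 6.11 ± 1.39 in young D2 (adjusted p = 0.00283). It was at least 471-fold lower by a bound that covers counting error only.

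**Figure D1:**
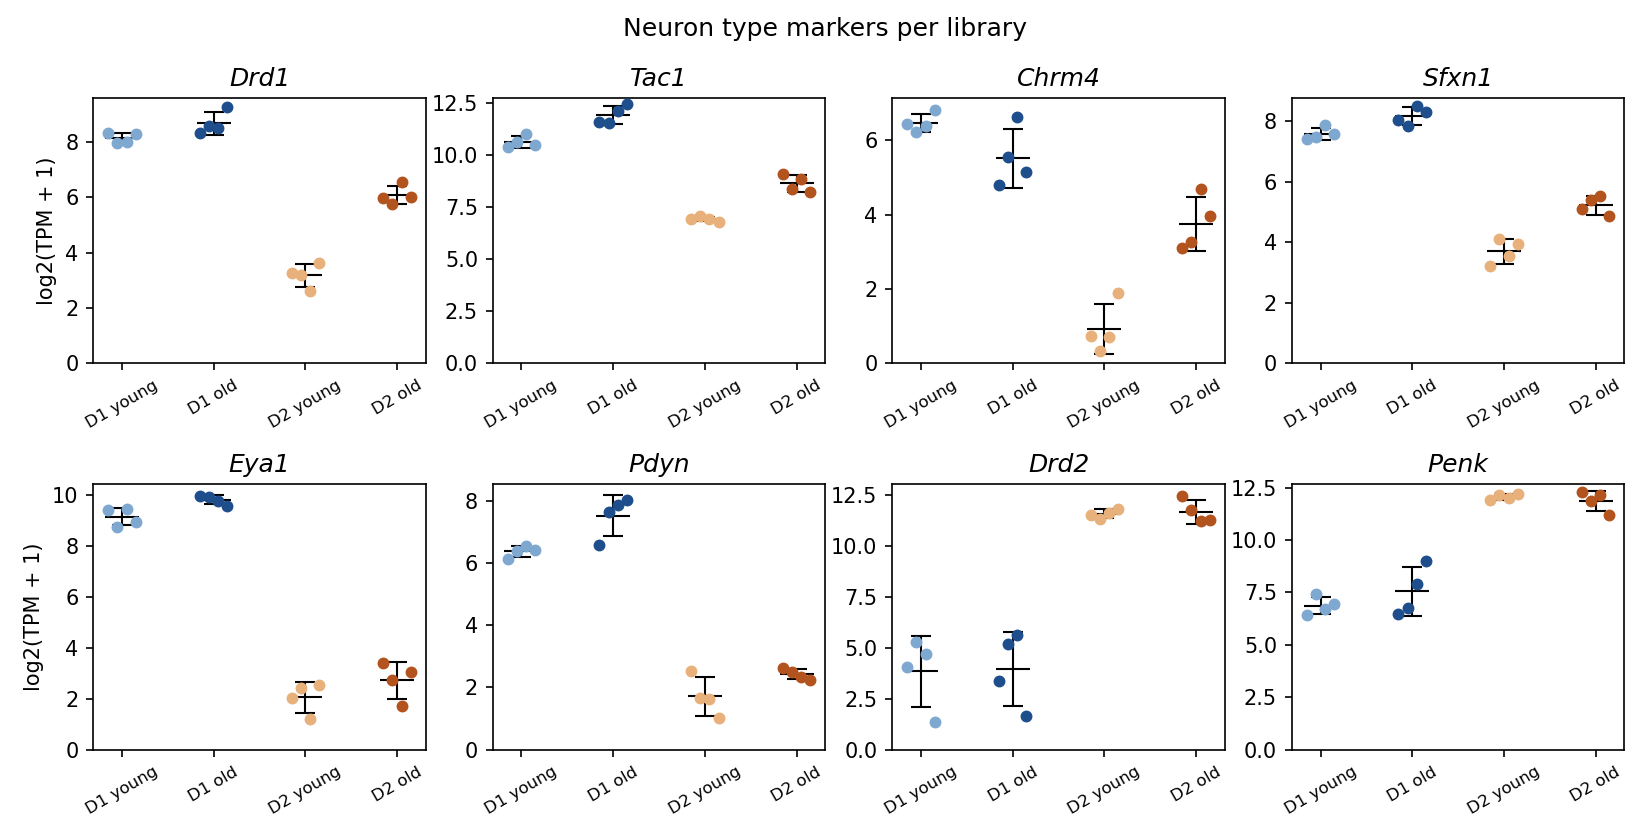
Marker genes of the neuron kinds in each of the 16 libraries, as log2(TPM + 1), with the mean and SD of each group of 4. Drd1 is 8.31 TPM in young D2 and 67.6 in old D2, while Drd2 runs from 2395 to 5717 over the D2 libraries.

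At 2 years the same question gave 1337 genes, 699 higher and 638 lower in D1, with 3534 at an unadjusted p under 0.05. The balance depends on the setting, with 481 higher and 1109 lower by limma-trend on TPM and 471 and 184 by voom with library weights. Eya1 (897 ± 107 against 6.22 ± 3.07; log2 7.25, adjusted p = 6.02e-09), Tac1 (log2 3.51, adjusted p = 3.83e-07), Pdyn (log2 5.62, adjusted p = 8.33e-07), Drd2 (log2 -7.13, adjusted p = 4.82e-05) and Penk (log2 -3.80, adjusted p = 6.2e-05) kept their direction. Drd1 stood at 418 ± 130 in D1 and 67.6 ± 16.7 in D2 (log2 2.77, adjusted p = 1.21e-05). Nexn, which codes for an actin-binding protein, was higher in old D1 at 664 ± 234 against 62.0 ± 7.14 (log2 3.58, adjusted p = 4.17e-07). Genes called at both ages in the same direction numbered 22 higher in D1 (1.41 expected by chance) and 17 lower (1.33 expected).

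As at 42 days, D1 markers were higher in D1, 9 of 10 (camera adjusted p = 2.14e-16; adjusted p = 2.03e-04 with an estimated correlation), and D2 markers lower, 8 of 9 (adjusted p = 1.53e-08; adjusted p = 4.94e-04 with an estimated correlation). Cholinergic markers were lower with an adjusted p = 0.00456 (adjusted p = 0.0834 with an estimated correlation), and the other 23 lists did not pass. The gene count was 2402 with DESeq2, 354 with only the compared groups in the fit and 899 with the trend over GC content and length removed.

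What age changes in D1 neurons was asked next. Gad2, which makes the transmitter GABA, rose from 897 ± 275 to 2525 ± 526 (log2 1.43, SE 0.17, adjusted p = 8.84e-05), Tac1 from 1616 ± 324 to 4054 ± 1274 (log2 1.35, adjusted p = 0.00202), the chaperone Hsp90aa1 from 557 to 1619 (log2 1.44) and the glycolytic enzyme Aldoc, also on the astrocyte list, from 41.2 ± 16.2 to 278 ± 73.9. Nos1, the neuronal nitric oxide synthase and also on the GABAergic interneuron list, rose from 1.10 ± 0.54 to 12.8 ± 8.22 (log2 3.91, SE 0.78, adjusted p = 0.00371). Dlg4, a postsynaptic scaffold gene, fell from 1062 ± 216 to 417 ± 177 (log2 -1.64, adjusted p = 8.84e-05), the G protein subunit Gng7 from 1764 to 555 (log2 -1.26, adjusted p = 5.91e-04) and the antioxidant enzyme Gpx1 from 186 ± 31.6 to 31.57 ± 22.004 (log2 -2.67). These genes stayed called in the same direction in every alternative tried. In all 1508 genes were called, 750 higher and 758 lower, with 3745 at an unadjusted p under 0.05. The count was 2600 with DESeq2 (1180 higher and 1420 lower), 305 with only the compared groups in the fit (192 and 113), 547 by voom with library weights (392 and 155) and 766 with the GC and length trend removed (430 and 336), of which 544 were among the 1508.

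Drd1 itself went from 284 ± 36.7 to 418 ± 130 (log2 0.50, adjusted p = 0.25), and Pdyn from 82.2 to 195 (log2 1.18, adjusted p = 0.0588); neither was called. Abce1, a ribosome recycling factor, went from 26.7 to 33.6 (log2 0.24, adjusted p = 0.701). Ppp1r1b, the dopamine-regulated phosphatase inhibitor, fell from 3766 ± 407 to 1764 ± 367 (log2 -1.29, SE 0.16, adjusted p = 1.14e-04), a call that ends with the trend over GC content and length removed (log2 -0.29, adjusted p = 0.236). The same removal turns the glutamate receptor gene Gria2 from log2 0.92 to -0.15. Beta-2-microglobulin, B2m, rose from 8.97 ± 6.08 to 89.6 ± 64.8 (log2 3.38, adjusted p = 0.0233), and with the trend removed it stands at log2 2.92 with an adjusted p = 0.0561; the call also ends without young D1 replicate 1 (3.36) or old D1 replicate 2 (3.08). The thioesterase gene Acot8 (10.5 ± 5.59 in young D1) had no count in old D1, at least 249-fold lower by a bound that covers counting error only. Old D1 libraries held a count for 10356 to 13676 genes, against 12766 to 14974 in young D1. The bound does not cover genes missed in those libraries.

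By fixed lists, no list of 26 passed in D1 with camera (lowest adjusted p 0.0728; 5 at an unadjusted p under 0.05), and limma's fry called 8. Of 90 respiratory chain genes 6 rose and 22 fell (9 and 34 adjusted over the list alone). Among them Uqcrb rose from 253 to 1195 (log2 2.25) and Atp5a1 from 414 to 976, while Uqcr11 fell from 850 to 138 and Cox6a1 from 3405 to 677. Of 87 ribosomal protein genes 3 rose and 19 fell (6 and 24), with Rplp2 falling from 797 to 178 and Rps6 rising from 367 to 777. With the GC and length trend removed, camera's direction for these 2 lists turns from down to up (adjusted p = 0.540 for the respiratory chain and 0.300 for ribosomal proteins). Of 16 pan-SPN markers 2 rose and 4 fell (3 and 4). Of 18 antioxidant genes 2 rose and 4 fell (2 and 4), with Sod2 and Cat up and Gpx1 and Prdx5 down. Of 15 genes of ribosome recycling and rescue 2 rose and 2 fell (3 and 2), and of 10 genes of nonsense-mediated decay 2 rose and 1 fell (4 and 1).

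The remaining lists in D1 follow as genes higher and lower, with those adjusted over the list alone in brackets. Heat shock genes gave 2 and 0 of 9 (5 and 1), postsynaptic genes 2 and 3 of 15 (2 and 3), immature neuron genes 0 and 3 of 10 (0 and 3), immediate early genes 0 and 3 of 11 (0 and 4) and cholesterol synthesis genes 0 and 2 of 16. Nr4a1, an immediate early gene, fell from 47.0 to 5.87. The 3 immediate early calls end with the GC and length trend removed, with Nr4a1 still at log2 -2.13 (adjusted p = 0.0619), Egr4 at -1.27 (adjusted p = 0.407) and Arc at -0.52 (adjusted p = 0.575); Arc's ends also without young D1 replicate 2 or 4 or old D1 replicate 1, 2 or 3, and Egr4's without young D1 replicate 4. Sod2 shrinks from log2 1.11 to 0.42 (adjusted p = 0.325), and the calls of Cat (2.21), Rps6 (1.01) and Acot8 end with only the compared groups in the fit at about the same fold. Cat's call also ends without young D1 replicate 1 (adjusted p = 0.0526) or old D1 replicate 4 (adjusted p = 0.0544), and that of Rps6 without young D1 replicate 1 (adjusted p = 0.0745) or 4 (adjusted p = 0.0756). D1 markers gave 1 and 0 of 10 (2 and 0), astrocyte markers 1 and 0 of 10 (Aldoc), and interferon and MHC class I genes 1 and 0 of 6. The GABAergic interneuron list had 1 gene higher (Nos1), the endoplasmic reticulum stress and lysosome lists had 1 each, and the glutamatergic neuron list 1 lower (1 and 1). Markers of D2 neurons, oligodendrocytes, microglia, ependymal cells and cholinergic neurons, mitochondrially encoded genes, p53 targets and collagens had none.

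Called genes in D1 sorted by base composition. Those higher with age had a median GC content of 45.3% and those lower 56.2%, against 50% for all tested genes. Median lengths of the main isoform were 4151 and 2299 bases (2976 for all). Across genes the D1 age change correlated with GC content at a rho of -0.360, and at 0.0570 with the trend removed; in D2 it was -0.0130.

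**Figure D2:**
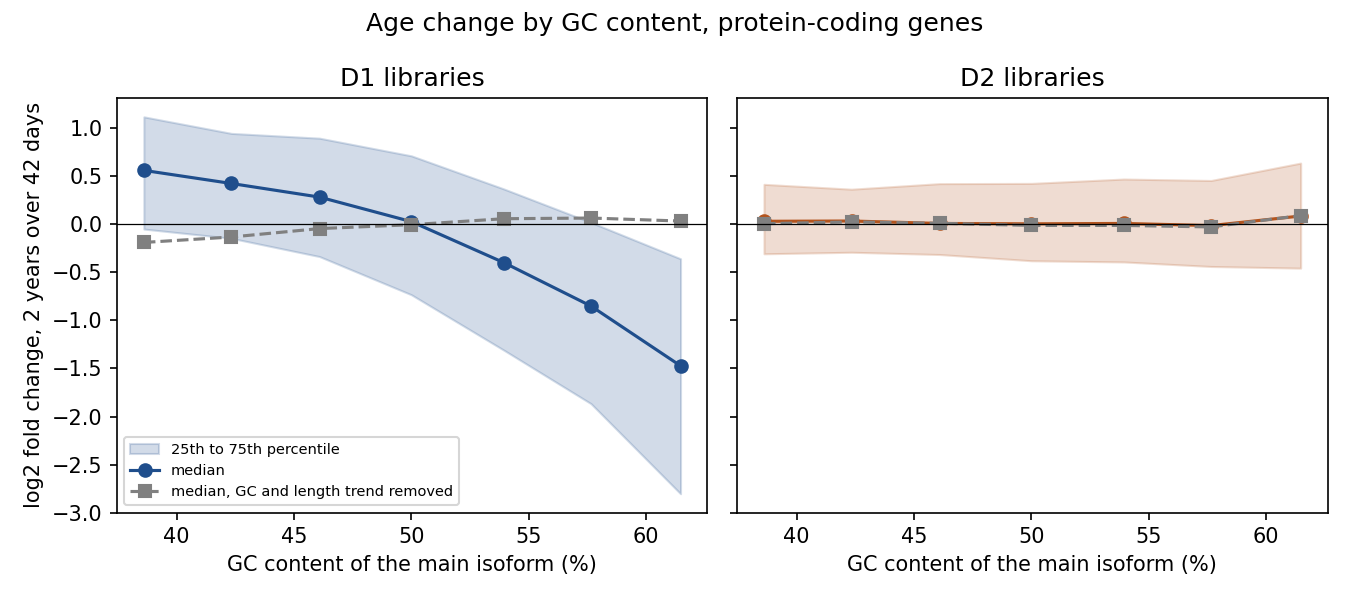
Age change (log2 fold change) by GC content of the gene in D1 and D2 neurons, as median with the 25th to 75th percentiles, before and after each library's trend over GC content and length was removed. In D1 the median runs from 0.56 at or under 40% GC to -1.47 above 60%.

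Fewer genes were called with age in D2 neurons than in D1. The test took 1 spread per gene over all 16 libraries, although libraries of old D1 correlated least with their own group. Drd1 rose from 8.31 ± 2.54 to 67.6 ± 16.7 (log2 2.95, SE 0.29, adjusted p = 2.86e-05), Tac1 from 122 ± 9.97 to 414 ± 119 (log2 1.70, SE 0.25, adjusted p = 0.00508) and the calcium sensor gene Hpcal4 from 216 ± 10.03 to 595 ± 95.8 (log2 1.37, SE 0.14, adjusted p = 2.86e-05). Rgs4, a regulator of G protein signalling, fell from 941 ± 47.9 to 361 ± 60.4 (log2 -1.47, SE 0.18, adjusted p = 5.99e-04), and the postsynaptic scaffold gene Homer1 from 289 ± 26.8 to 153 ± 46.9 (log2 -1.28, adjusted p = 0.0016). Chrm4, Sfxn1, Pea15a, Foxp2 and Impg1 rose as well, with Chrm4 going from 1.08 to 13.9 ± 7.94. In all 11 genes were called, 9 higher and 2 lower, with 801 at an unadjusted p under 0.05. DESeq2 called 102 (68 higher and 34 lower), fits on only the compared groups 39 (21 and 18) and voom with library weights 167 (77 and 90). In D1 the last 2 settings gave 305 and 547. Drd1, Tac1, Hpcal4 and Rgs4 stayed called in every alternative, and each of the others named lost its call in at least 1, such as with 1 library left out. Drd2, Penk, Adora2a and Abce1 each had an adjusted p of 1.

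In D2, 9 of the 26 lists passed, a number that another split of the same libraries also reached. D1 markers rose (adjusted p = 1.33e-17; adjusted p = 1.42e-04 with an estimated correlation), with 4 of 10 higher and 7 when adjusted over the list alone. Astrocyte markers rose (adjusted p = 7.51e-05; adjusted p = 0.0458 with an estimated correlation), as did interferon and MHC class I genes (adjusted p = 0.00339; adjusted p = 0.0458 with an estimated correlation). In these 2 lists 0 genes were called by edgeR and 1 each when adjusted over the list alone, and 9 of 10 and 4 of 6 had a positive change. Passing with the preset correlation only were pan-SPN markers, lower (adjusted p = 3.24e-04; adjusted p = 0.123 with an estimated correlation), respiratory chain genes, lower (adjusted p = 3.24e-04; adjusted p = 0.263 with an estimated correlation), and immediate early genes, lower (adjusted p = 0.00339; adjusted p = 0.297 with an estimated correlation). The same holds for cholesterol synthesis, higher (adjusted p = 0.00211; adjusted p = 0.0609 with an estimated correlation), lysosome genes, higher (adjusted p = 0.00353; adjusted p = 0.144 with an estimated correlation), and microglia markers, higher (adjusted p = 0.00724; adjusted p = 0.144 with an estimated correlation). The other 17 lists did not pass.

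Whether the age change differs between the kinds was tested directly. Nexn (179 to 664 in D1, 97.2 to 62.0 in D2; log2 difference 2.58, adjusted p = 0.00499), Higd1a, a mitochondrial gene (141 to 511 and 214 to 135; 2.56, adjusted p = 0.00574), and Bod1l (2.37, adjusted p = 0.00499) had the more positive age change in D1. Drd1 (-2.45, adjusted p = 0.00561) and Chrm4 (-4.43, adjusted p = 0.00953) had the more positive age change in D2. These 5 stayed called in every alternative. In all 246 genes differed, 129 with the more positive change in D1 and 117 with the more positive change in D2, with 2353 at an unadjusted p under 0.05. That balance was 140 and 42 by voom with library weights, 65 and 20 with the GC and length trend removed and 66 and 124 by limma-trend on TPM. Gad2 (1.47, adjusted p = 0.00574) is called here, and with the GC and length trend removed it stands at 0.91 (adjusted p = 0.0833). No list of 26 passed with camera (lowest adjusted p 0.0939; 5 at an unadjusted p under 0.05), and fry called 2. Across genes the 2 age changes correlated at r 0.0623 (rho 0.0921), and 5 genes were higher with age in both kinds against 0.485 expected.

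Isoforms of coding genes were compared in 3 ways with exact two-sided permutation tests of 4 against 4 libraries. The median log2 abundance-weighted length changed by -0.000166 in D1 (exact p = 0.886) and 0.000306 in D2 (exact p = 0.914) over 9235 genes. A median over genes hardly moves when a minority of genes changes, so it does not exclude changes in some genes. The mean over genes changed by log2 -0.0157 in D1 (exact p = 0.400) and -0.00117 in D2 (exact p = 0.943). The share of counts on isoforms without a coding sequence was 4.11 ± 0.30% in young D1 and 4.72 ± 0.51% in old D1 (exact p = 0.0857), and 3.77 ± 0.20% and 3.62 ± 0.22% in D2 (exact p = 0.371). The part on 144 isoforms inside a 3' UTR was 0.176 ± 0.030% and 0.269 ± 0.062% in D1 (exact p = 0.0571), and 0.183 ± 0.030% and 0.176 ± 0.0075% in D2 (exact p = 0.914). The largest of these in D1 by added counts was an isoform of Zfp365. It stood at 700 ± 112 in young and 1134 ± 371 in old, in CPM over the counts of protein-coding genes alone. Its rise of 434 was a large part of the D1 rise, against 85.0 for the next isoform, of Phactr1. The largest fall was -61.9, for an isoform of Dnm1.

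**Figure D3:**
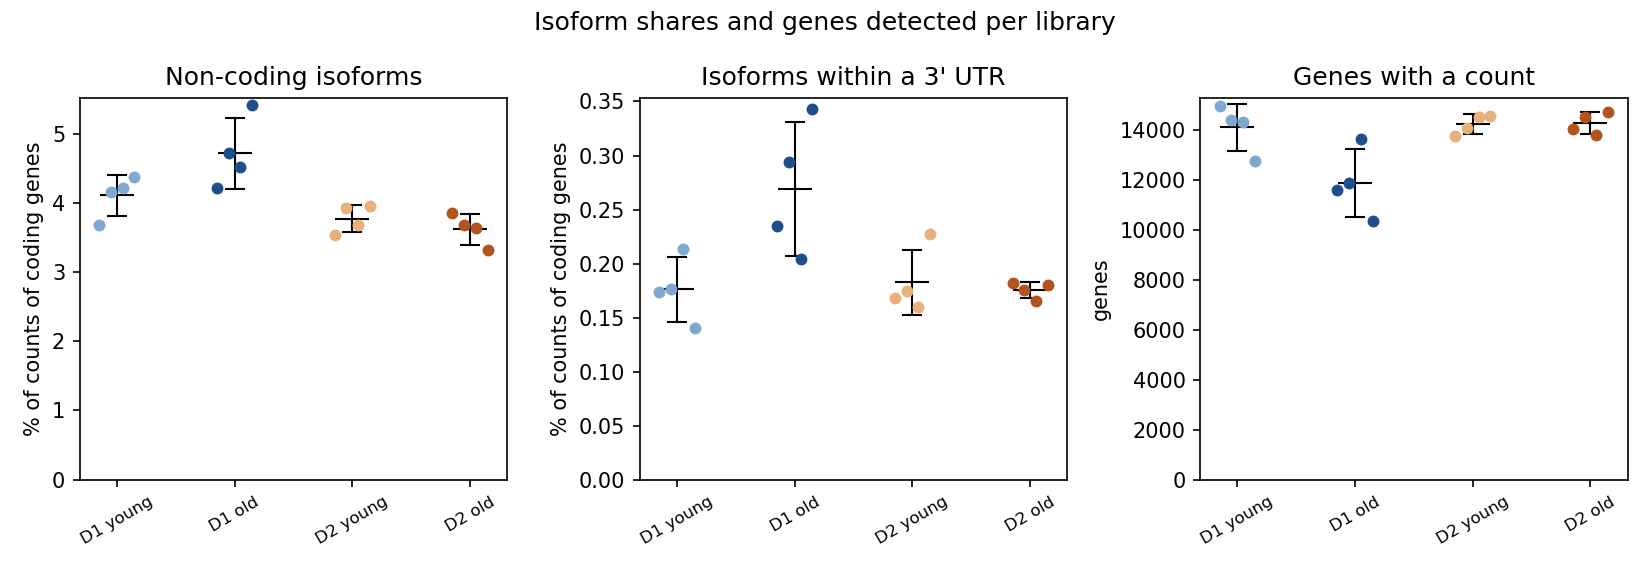
Per library, the share of counts on isoforms without a coding sequence, the share on isoforms inside a 3' UTR (both in percent) and the number of genes with a count, by group, with mean and SD. The old D1 libraries hold 10356 to 13676 genes with a count.

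Use of isoforms differed between the ages in 417 of 6426 genes tested in D1 (1890 at an unadjusted p under 0.05) and in 2 in D2 (500). The old D1 libraries held a count for 15620 to 25145 isoforms, against 24493 to 31572 in the other groups. By isoform, 447 fell and 70 rose in D1 relative to their gene. Isoforms missed in the old D1 libraries and an effect of age cannot be told apart here. In D1 an isoform of Clvs1 went from 30.7 ± 8.8% of its gene to 0 (adjusted p = 8.47e-16) and one of the phosphate carrier gene Slc25a3 from 29.0% to 0.0098% (adjusted p = 6.11e-10), while an isoform of Chn1 rose from 0 to 28.1 ± 19.0% (adjusted p = 2.49e-06). In D2 the genes were Sgip1 (adjusted p = 1.51e-04) and Mkks (adjusted p = 0.0406), each with an isoform at 0 in young that reached 4.36% and 28.9 ± 13.9% in old.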

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

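The tests of index sets and of D1 libraries mixed into old D2, and the removal of the trend over GC content and length, were chosen only after the result was seen. The rule that a correlation of at least 0 must also exceed its spread before it excludes a cause was set after the r values were seen.

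A sample was listed here when its gap to the nearest of the other 3 in its group took up most of the group's range, by Dixon's test at 95%, which chance gives in about 1 in 20 groups. Of 32 groups of library measures 1 was listed: the share of the most abundant gene in old D1 replicate 4, at 4.45%. Of 313 groups of gene values 24 were, or 7.67%. In young D1 they were Rfx2 in replicate 3 (25.7 TPM), Nme4 (86.1), Cox6a1 (4864), Dnajb1 (147), Grin1 (313) and Bod1l (11.8) in replicate 4, Gtpbp1 in replicate 2 (119), Hspa5 (57.1) and Abce1 (38.8) in replicate 1, and Dlg4 (738) and Shank3 (25.2) in replicate 3. In old D1 they were Shank3 (86.3), Adora2a (37.6), Ebf1 (86.1) and Tbr1 (139), all in replicate 4. In young D2 they were B2m (58.9), Slc35d3 (5.64) and Tbr1 (0.61) in replicate 4, Gtpbp1 in replicate 1 (101), Gria2 in replicate 3 (183) and Nnat in replicate 2 (523). In old D2 they were Il33 in replicate 2 (6.42), Foxp2 in replicate 1 (154) and Homer1 in replicate 3 (223).

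Other results are listed because the difference between the age changes of D1 and D2 passed its test. These are the 246 genes as a count, the share of counts on isoforms without a coding sequence (0.759 percentage points, exact p = 0.0306) and the share on isoforms inside a 3' UTR (0.09997 percentage points, exact p = 0.0327). For the shares, age labels were permuted within each kind, which assumes no age effect in either kind. These exact p-values therefore do not test equal age changes alone. Neither share passed within D1 or within D2, so a difference between the kinds is not established for the shares. Among named genes the log2 difference was above 0 for Rrs1 (2.95), Spag7 (2.79), Nexn (2.58), Higd1a (2.56), Zcchc9 (2.41), Rpf2 (2.39), Bod1l (2.37), Gad2 (1.47), Hsp90aa1 (1.38), Atp5a1 (1.15), Homer1 (1.048) and Gnal (1.005). It was below 0 for Chrm4 (-4.43), Tubb3 (-2.71), Drd1 (-2.45), Prdx5 (-2.40), Cox6a1 (-2.25), Uqcr11 (-2.24), Rplp2 (-2.21), Gpx1 (-2.12), Dlg4 (-1.36) and Ppp1r1b (-0.996). For Acot8, which had no count in old D1, the fitted value of -10.2 depends on the prior count and is no bound. Of these genes Nexn, Higd1a, Bod1l, Drd1 and Chrm4 stayed called in every alternative and each of the others lost its call in at least 1. With the trend over GC content and length removed, Ppp1r1b stands at -0.13 (adjusted p = 0.868), Dlg4 at -0.34 (0.581), Uqcr11 at -0.90 (0.308), Gpx1 at -1.25 (0.248) and Cox6a1 at -0.99 (0.212).

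The first pattern weighed is the 1508 genes changed with age in D1. Chance is argued against for this count, with 26 genes as the highest of the other 34 splits of the 8 libraries. The real split can at best be 1 of 35. The other splits mix the real groups, so a real difference adds to the spread within them. A bias over GC content and length could be behind part of it: 36.1% of the called genes stayed called in the same direction once that trend was removed, 96.8% kept their sign, and the median log2 change in the called direction was 1.11 after, against a median absolute change of 1.55 before. Fewer distinct molecules in the old D1 libraries would need the score of these genes to fall with the number of genes with a count; within the other groups r was 0.353, the other direction, too uncertain to decide (exact p = 0.477; rho 0.119, exact p = 0.759; r -0.182 without the 2 farthest). Of the old D1 libraries 0 share the second part of their index with young D1, so these causes and an effect of age cannot be told apart for the group as a whole.

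The second is the share of D1 counts on isoforms inside a 3' UTR, whose rise did not pass within D1 (exact p = 0.0571). Annotated retained introns are argued against as the source, since the isoforms not annotated as such had 1.79 times the young share in old D1, against 0.924 for those that are. The split rests on annotation, so unspliced RNA or introns that are not annotated stay open. All retained intron isoforms of coding genes held 1.86% of counts in young D1 and 1.99% in old D1 (exact p = 0.429). Processed transcripts without a coding sequence held 2.25% and 2.73% (exact p = 0.0286). The Zfp365 isoform, not annotated as a retained intron, made up a large part of the added share. Shorter fragments in old D1 could move fragments onto isoforms inside a 3' UTR. Within the other groups the share against fragment length gave r -0.369, the direction this needs but too uncertain to decide (exact p = 0.286, rho -0.322 with exact p = 0.390, r -0.412 without the 2 farthest). That effect and an effect of age cannot be told apart, because all old D1 libraries have shorter fragments than the other 12.

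The third is the higher level of D1 markers in old D2 libraries. Mixing of D1 libraries at 1 common share leaves Eya1 and Pdyn unexplained. The source was the lower of the young and old D1 means. The median share was 19.0% over the 28 genes called higher in D1 than in D2 at 42 days. Single shares ran from -49.3% (Pcp4) to 655% (Lrrn2). These genes were picked in part for low values in young D2, which can raise the shares, and the levels needed below rest on this median. At that share Eya1 would stand at 112 TPM and was seen at 6.22, and Pdyn would stand at 17.65 and was seen at 4.39. These 2 of the 10 markers have an upper bound under 0.25 times that share, Pdyn narrowly (upper share 4.51%). Ebf1 (6.73 needed, 1.87 seen, upper share 7.16%) and Sfxn1 (46.4 and 36.8, 18.4%) also lie below the needed level. Others lie near it, such as Tac1 (406 needed, 414 seen), Drd1 (60.7 and 67.6), Isl1 (11.3 and 11.2) and Slc35d3 (13.7 and 12.3). A first version of the test over 28 genes decided nothing. The marker version was set after those shares were seen, so its count of 2 markers gives no verdict, and mixing as a part of the cause stays open. More unbound tissue RNA in the pulldown could raise them, and markers of oligodendrocytes, microglia and endothelium had a median log2 change of 0.649 (0.0086 to 1.03 by bootstrap over 24 genes) against 1.60 for D1 markers. By list the medians were 0.222 for oligodendrocyte markers (12 genes) and 1.69 for microglia markers (10 genes). Astrocyte markers, not part of that test, had a median of 1.09. Unbound tissue RNA and an effect of age on D2 neurons cannot be told apart, since these medians do not separate a bulk effect from a change in D2 neurons.

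Chance is argued against for the count of genes changed with age in D2 (11, highest other split 0). The same holds for genes that differ between the kinds in young mice (57, highest other 0) and in old mice (1337, highest other 4). It also holds for isoform use with age in D1 (417, highest other 76). For each of these the real split was the only 1 of 35 as large, the smallest share that 35 splits can give. No correction was made for the number of counts tested. For the 246 genes whose age change differs, 2 of 100 splits were as large, and the other gave 374 genes. It left the D1 age groups whole, with 6 of 8 D2 libraries sorted by age in 1 direction or the other. Other splits with the D1 age groups whole gave 168 genes (6 of 8 D2 libraries sorted) and 205 genes (4 of 8). The count was thus large whenever the D1 age groups were whole, and the splits do not show that it depends on the D2 age labels. For the lists with age in D1 (0 lists; highest other 4) and for the difference (0; highest other 6) the real count is 0, so 35 of 35 and 100 of 100 splits are as large by construction and the splits say nothing about chance. Chance cannot be excluded for the number of lists passing in the other contrasts. For age in D2, 2 of 35 splits were as large (9, highest other 9), in young 2 of 35 (9, highest other 9) and in old 13 of 35 (3, highest other 5). These splits weigh the number of lists at the preset correlation and say nothing about any 1 list. Nor can chance be excluded for isoform use in D2, with 30 of 35 (2, highest other 10).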

How the results depend on the processing

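The removal of the GC and length trend, voom with library weights (except for the difference) and leaving out the fewest-gene libraries were tests chosen only after the result was seen.

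Of 203 named gene calls 74 were kept under every alternative, and 2982 of 3663 values under alternatives were still called in the same direction. DESeq2 gave 2600 genes for age in D1, 102 for age in D2, 1019 for the difference, 187 in young and 2402 in old; fits on the compared groups alone gave 305, 39, 98 and 354 (the difference needs all groups). Voom with library weights gave 547, 167, 203 and 655. Trend removal gave 766 for age in D1 and 85 for the difference. Leaving out the fewest-gene libraries gave 21 for age in D2, 234 for isoform use in D1 and 1 in D2, and limma's diffSplice gave 1235 and 37. Lists passing were 8, 4, 2, 5 and 6 with fry (age in D1, age in D2, difference, young, old); 3 and 3 with an estimated correlation (age in D2, young); 1 and 3 with the trend removed (age in D1, difference); and 3 for age in D1 without the fewest-gene libraries. The mean of per-gene shares gave 2.53 and 6.88 percentage points for the 2 isoform shares in D1, each with the smallest exact p possible, 0.0286.

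With 1 library left out the counts were 909 to 2055 for age in D1, 5 to 12 for age in D2, 66 to 656 for the difference, 40 to 47 in young, 692 to 1873 in old, 239 to 458 for isoform use in D1 and 1 to 3 in D2. Lists were 0 to 3, 7 to 10 and 0 to 1 for the age contrasts. The isoform shares in D1 were 0.375 to 0.775 and 0.0683 to 0.115 percentage points, those in D2 -0.230 to -0.0504 and -0.0145 to 0.00786, and lengths -0.000636 to 0.000714 in D1 and -0.000764 to 0.00111 in D2; these exact tests cannot pass below 0.0571. Counts moved over 1.5 times without young D1 replicate 1, 2 or 4 (919, 987, 909), without young D2 replicate 1, 2 or 3 (6, 6, 5) or old D2 replicate 4 (7), and without old D2 replicates 2, 3 and 4 in old (692, 784, 869). The difference moved without young D1 replicate 1, 2 or 4 (103, 129, 111), young D2 replicates 1 to 4 (127, 84, 136, 75), old D2 replicates 2, 3 and 4 (66, 113, 145) and old D1 replicate 3 (656). Isoform use moved without young D1 replicate 1 (246) or old D1 replicates 1, 2 and 4 (239, 254, 251), and lists without old D1 replicate 4 (3). Gria2 turned with the trend removed (-0.15, adjusted p = 0.736), and Adora2a with age in D1 without old D1 replicate 4 (-3.14, adjusted p = 0.0369; -3.14 to 0.52 over libraries left out). The cause was not tested.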

Other observations

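The counts of isoforms below were tests chosen only after the result was seen.

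Isoforms that hold at least 10% of a gene in every library of one group and have no count in any library of another were counted over 37704 isoforms of genes with a mean of at least 10 CPM. Against old D1, 57 isoforms of young D1, 68 of young D2 and 89 of old D2 (88 genes) met this. Isoforms present in old D1 and absent elsewhere numbered 13 against young D1, 18 against young D2 and 20 against old D2. All pairs of the other groups gave 1 to 3.

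Over all 21625 isoforms tested in D1, 70 rose and 447 fell relative to their gene at an adjusted p per isoform under 0.05 (diffSpliceDGE). Of these 15 and 38 have no coding sequence, as do 5676 of the 21625. The old D1 libraries held a count for 15620 to 25145 isoforms against 24493 to 31572 in the other 12. An isoform of the phosphodiesterase gene Pde10a went from 6.73% to 0, of Atg13 from 47.1% to 0, of Rgs8 from 12.8% to 0, of Ndufs7 from 43.4% to 0, of Slc22a23 from 60.6% to 0 and of Ripor2 from 71.2% to 0.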
